A study of Rattus norvegicus with 6 samples.

How the data were processed

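Prostate tissue from rats (Rattus norvegicus) was profiled by RNA sequencing in 6 libraries, 3 from rats that carried subcutaneous pellets of testosterone and estradiol and 3 from rats that had a skin incision and stapling without pellets. The sample titles and the treatment labels give these groups. One label field names benign prostatic hyperplasia for all 6 samples, controls included, and was not used for grouping. The titles number the tissues 1 to 3 in each group, and nothing in the labels says that each tissue came from a separate animal, so the p-values measure the spread between these tissues.

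Per the labels' protocols, total RNA was isolated with a column kit (RNeasy mini) and paired-end libraries were made with the TruSeq RNA kit. Per the submitters' processing notes, TopHat, Bowtie2 and HTSeq were used, with no versions. The genome build, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The authors deposited a table with raw read counts per gene and, beside them, FPKM values (counts scaled by gene length and library total) for the same libraries. In the deposited table, FPKM equalled the count divided by a gene length and by the library's count total, with a largest relative deviation of 0.0169% over 10222 genes. FPKM was therefore a rescaled count with no further normalisation. Gene symbols, Ensembl identifiers and coordinates are those of the table. The table held 32883 genes, of which 13031 had no count in any library, and it held 0 columns of other samples.

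Total counts ranged from 12931982 in control 1 to 15949500 in hormone 1. A count of 0 allows a level of up to 0.188 CPM (counts scaled by library total) in hormone 1 and 0.232 CPM in control 1 (3 counts per library). Intervals and floors cover counting error only.

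Raw counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr (minimum count 10, minimum total count 15), which left 14003 genes holding at least 99.8% of the counts of each library. Libraries were scaled with TMM, and the quasi-likelihood F-test (glmQLFit and glmQLFTest, robust) compared hormone with control, with no block and 4 residual degrees of freedom. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. Levels are TMM-scaled CPM, given as mean ± SD with n = 3 per group. Log2 fold changes are hormone minus control. Their standard errors (SE) are the fold change divided by the square root of the F statistic.

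Gene lists with 37 themes, covering hormone response, secretion, proliferation, signalling, metabolism and the cell types that prostate tissue can hold, were fixed with the test before the data were examined. They were tested with camera (limma 3.58.1) on the same counts and dispersions, with a preset correlation of 0.01, for lists with at least 5 genes tested and with Benjamini-Hochberg adjustment over lists. Camera asks whether the test statistics of a list's genes are on average higher or lower than those of the other genes, and a version on ranks was an alternative. It was repeated with a correlation estimated for each list, and fry was run as an alternative that tests a list without reference to other genes.

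The rule for named genes was fixed at the same time. It names the 12 highest and 12 lowest log2 fold changes among called genes whose 3 hormone and 3 control values do not overlap, with a mean FPKM of at least 5 in the higher group and an established symbol. It also names 18 genes chosen in advance, up to 4 members with the smallest p of each list past camera and up to 2 members of each other list. Of these, the text gives values for a part and counts for the rest. Some genes that the rule names are not reported here.

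The share of counts taken by secretory transcripts was compared with an exact permutation test, two-sided, whose smallest possible p for 3 against 3 is 0.1. Similarity was described with principal components and correlations of log2 CPM (prior count 2). Counts of every pair of libraries within a group differed far beyond sampling noise, with a chi-square per gene of 22.3 to 112, so no library was counted as a duplicate.

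The test was run on simulated data, with counts drawn for the 14003 genes from the real means, dispersions and library sizes. Of 50 genes raised 4-fold it called 88%, and of 50 genes raised 2-fold it called 32%. It also called 11 genes that had not been changed, among 132 calls. A simulated list of genes raised 1.5-fold was found by camera, and 0 of 35 unshifted lists were called. The simulated genes were drawn independently, so this does not test camera under the correlation of real lists, where the estimate reached 0.818 and 9 to 19 lists passed in the other splits of the libraries. Those splits mix hormone and control libraries and keep part of any group difference.

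Alternatives were DESeq2 size factors, quantile normalisation, no filter, a filter on FPKM of at least 5 in at least 3 libraries, DESeq2 1.42.0 in place of edgeR, limma on log2(FPKM + 1), log2(FPKM + 0.1) or log2(FPKM + 5) for genes with FPKM of at least 1 in at least 3 libraries, a replicate block, an adjusted p under 0.01, a 1.5-fold minimum (glmTreat), and each library left out. Camera on log2 CPM and camera after removal of a loess trend against gene length (span 0.3) were added after seeing the data.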

Results

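Rat prostate RNA was compared in 6 libraries, 3 from rats carrying hormone pellets and 3 from control rats. Over 4 weeks each hormone rat carried 4 pellets under the skin, each holding 25 mg of testosterone together with 2.5 mg of estradiol, a treatment used to induce benign prostatic hyperplasia, and control rats had only an incision and staples. The comparison asked which transcripts differed between prostates under excess testosterone and estradiol and prostates without it. Total counts were 12931982, 15809858 and 15496574 in controls 1 to 3 and 15949500, 14253511 and 13744680 in hormone libraries 1 to 3. Between 17165 and 17741 genes had at least 1 count in each library.

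Ifitm6, Zbtb40, Gcnt3 and Rbp7 were among the genes with the highest fold changes under the pellets. Ifitm6, of the interferon-induced transmembrane family, rose from 3.99 ± 1.38 to 439 ± 201 CPM (SD, n = 3 per group), a log2 fold change of 6.77 ± 0.44 (SE; edgeR adjusted p = 0.00234). The zinc finger gene Zbtb40 rose from 23.6 ± 0.91 to 1664 ± 804 CPM, 70.4-fold (adjusted p = 0.00268). Gcnt3, an enzyme that builds branched mucin-type O-glycans, rose from 5.35 ± 1.60 to 262 ± 81.6 CPM, 49.0-fold (adjusted p = 0.00157). Rbp7, a cellular retinol-binding protein, rose 33.8-fold, from 1.52 ± 0.52 to 52.1 ± 17.7 CPM. In the table's coordinates, Ifitm6 (ENSRNOG00000036645) lies on chromosome 1 at 213817312 to 213818222 and Zbtb40 (ENSRNOG00000022039) on chromosome 5 at 155346965 to 155381732. Gcnt3 (ENSRNOG00000059540) lies on chromosome 8 at 76449081 to 76452554 and Rbp7 (ENSRNOG00000015850) on chromosome 5 at 166278187 to 166282831. Ifitm6 belongs to a family of similar genes, and how the counting treated reads shared within such families is not given in the sources used here.

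Other genes of the 12 with the highest fold changes were almost without counts in controls. Csn2, the milk protein beta-casein, had 258 counts over the hormone libraries and 2 over the controls, a ratio of 141 with a 95% counting interval of 38.7 to 1172. For the zinc transporter Slc39a2 the counts were 479 and 3, a ratio of 175 (59.4 to 850), and for Prr32 they were 493 and 3, a ratio of 180 (61.2 to 875). Rnase1l1, a ribonuclease gene, had 1311 and 3 counts, but its hormone libraries spread from 2.73 to 65.7 CPM, and the ratio of 478 (163 to 2322) describes counting error only. Esrrb, which encodes an orphan nuclear receptor related to the estrogen receptors, reached 12.4 ± 9.16 CPM from 0.0856 ± 0.15 CPM (log2 fold change 7.04, adjusted p = 0.0175). Esrrb and Rnase1l1 lost their calls without any 1 control, hormone 1 or hormone 2 (adjusted p up to 0.078 and 0.11), and Slc39a2 without control 2 (0.0696). Hapln2, C2cd4b and Brinp2 completed the set, with log2 fold changes of 6.75, 6.68 and 4.82 and adjusted p values of 0.00943, 0.00428 and 0.00329.

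Wfdc18 and Col24a1 were among the 12 genes with the lowest fold changes. Wfdc18, a small secreted protein of the whey acidic protein family, fell from 231 ± 131 to 8.62 ± 5.91 CPM, 26.5-fold (adjusted p = 0.0148). Col24a1, a fibrillar collagen, fell from 130 ± 80.4 to 6.51 ± 1.45 CPM, 19.9-fold (adjusted p = 0.0082). Kera, the small leucine-rich proteoglycan keratocan, fell from 19.0 ± 14.8 to 0.686 ± 0.67 CPM (adjusted p = 0.0316). Havcr1, a membrane glycoprotein known as kidney injury molecule, fell from 694 ± 230 to 184 ± 82.4 CPM, and the chloride-bicarbonate exchanger Slc26a3 fell from 39.5 ± 6.30 to 10.3 ± 2.60 CPM. The sphingolipid desaturase Degs2, Cmahp, the lipolysis inhibitor G0s2, Nuggc, the calcium-binding protein Pvalb and Fez1 had log2 fold changes between -3.10 and -1.94. Wfdc18 did not pass without control 2 or hormone 2 (adjusted p up to 0.0724), and Kera and Havcr1 each lost their call without control 2, any hormone library and 1 other control (up to 0.13 and 0.16). With 1 library left out, Degs2, Cmahp, Pvalb, Nuggc and G0s2 also lost their calls, without any hormone library for Degs2, Cmahp and Pvalb, without hormone 1 or 2 for Nuggc and without hormone 2 or 3 for G0s2 (up to 0.131, 0.0838, 0.0832, 0.123 and 0.0583 in this order). Without control 2 Degs2, Cmahp, Pvalb and Nuggc did not pass either, nor did Degs2 without control 1, while Fez1 passed in every set. In these coordinates Wfdc18 (ENSRNOG00000037097) spans 71008709 to 71010863 of chromosome 10, inside the unnamed gene AABR07030143.1, which had 5 counts over all libraries. Col24a1 (ENSRNOG00000014143) spans 251200686 to 251434932 of chromosome 2.

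In total, 458 of 14003 genes tested passed an adjusted p under 0.05, 334 higher and 124 lower in the hormone group, and 259 of the higher and 70 of the lower genes differed at least 2-fold. The biological coefficient of variation was 22.7%. The hormone and control values did not overlap for 31.3% of the genes tested, where chance gives 10%. DESeq2 gave 906 higher and 618 lower genes, and limma on log2(FPKM + 1) 174 and 134, so that 59.4% and 56.5% of the calls were higher, against 72.9% with edgeR. The counts changed with the library left out, with 51 higher and 13 lower genes without control 2 and 313 and 150 without control 1. They were 296 and 156 without control 3. Without hormone 1, 2 or 3 they were 98 and 21, 102 and 12, and 98 and 13. Each of these fits had fewer residual degrees of freedom. Without control 2, the controls left were the least alike pair within a group (Pearson correlation 0.954). A call lost in this way does not by itself show that the library left out carried the difference. Of the 24 genes with the highest and lowest fold changes, 13 still passed without control 2, 16 without hormone 1, 13 without hormone 2 and 17 without hormone 3. Those that passed in every set were Ifitm6, Zbtb40, Gcnt3, Rbp7, Prr32, Csn2, Hapln2, C2cd4b, Brinp2, Col24a1, Slc26a3 and Fez1.

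**Figure D1:**
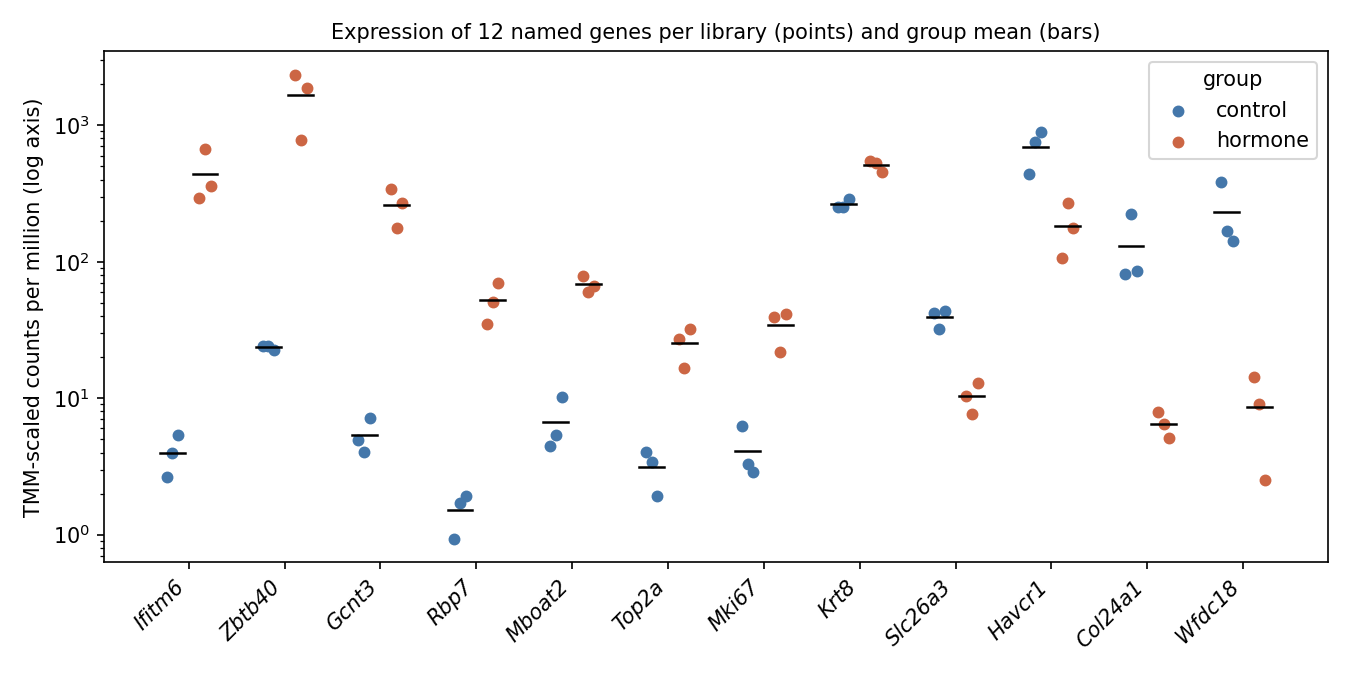
Expression of 12 named genes in TMM-scaled CPM on a log axis, with 1 point per library (3 control, 3 hormone) and a bar at each group mean. The groups do not overlap for any of these genes. Zbtb40 has means of 23.6 in controls and 1664 in hormone libraries, and Wfdc18 has means of 231 and 8.62.

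The cell cycle list stood out among the 37 gene lists. Of its 33 members tested, 21 rose and 0 fell over all genes tested (31 rose when adjusted over the list alone), with a median log2 fold change of 1.71. DESeq2 called 29 of the 33 members higher, with a median of 1.71. With limma the median was 0.92 on log2(FPKM + 1), 1.31 on log2(FPKM + 0.1) and 0.41 on log2(FPKM + 5), with 14, 13 and 11 of 29 members higher. The added constant shrinks fold changes of genes with low FPKM (control means 0.44 for Mki67 and 0.52 for Top2a). These medians are therefore not on the scale of the edgeR median. With FPKM of at least 5 the edgeR median was 0.77 over 5 members, 2 of them higher. Mki67, the proliferation marker Ki-67, rose from 4.13 ± 1.81 to 34.3 ± 10.8 CPM, 8.34-fold (adjusted p = 0.0109). Top2a, the DNA topoisomerase of dividing cells, rose from 3.13 ± 1.10 to 25.2 ± 7.86 CPM, 8.04-fold (adjusted p = 0.00966). The nucleotide synthesis genes Tk1 and Rrm2 had log2 fold changes of 1.65 ± 0.19 and 4.30 ± 0.49, and the replication helicase subunit Mcm3 had 1.79 ± 0.21 (adjusted p = 0.00943 for all 3). Pcna, the replication clamp, had 25.6 ± 2.53 CPM in controls and 35.0 ± 1.68 CPM in hormone libraries and did not pass (log2 fold change 0.45, adjusted p = 0.0978). Only DESeq2 called Pcna (adjusted p = 0.0221). Camera gave an adjusted p of 3.42e-36 for the list, and adjusted p = 0.0635 with an estimated correlation. Without control 2 the median was 1.70 and 0 members passed, with adjusted p values of 0.0533 for Top2a and 0.0586 for Mki67. Without hormone 1, 2 or 3, 10, 10 and 8 members passed.

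The estrogen receptors gave few calls. Esr2, estrogen receptor beta, had 18.8 ± 12.3 CPM in controls and 21.4 ± 4.39 CPM in hormone libraries and did not pass (adjusted p = 0.84). Esr1, estrogen receptor alpha, had 34 counts over the controls and 27 over the hormone libraries, too few to be tested. Gper1, the membrane estrogen receptor, was the 1 member of 22 that passed in the list of steroid receptors and steroid metabolism, falling from 6.08 ± 3.87 to 0.599 ± 0.17 CPM (adjusted p = 0.0342; camera adjusted p = 0.274 for the list). Its span overlaps LOC498154, and its call was lost without control 2, control 3 or any hormone library, with an adjusted p of up to 0.139. The 5-alpha reductases Srd5a1 and Srd5a2, which convert testosterone to dihydrotestosterone, had log2 fold changes of -0.50 and -0.52 (adjusted p = 0.168 and 0.288). Pgr, the progesterone receptor, had -1.26 (adjusted p = 0.373), and Prlr, the prolactin receptor, 1.38 (adjusted p = 0.117). Prlr passed with DESeq2 and without control 3.

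Of 30 androgen-responsive genes, 2 rose and 0 fell (4 and 1 when adjusted over the list alone). Eaf2, an elongation factor-associated protein, rose from 19.0 ± 2.79 to 72.5 ± 4.97 CPM, and Mboat2, a lysophospholipid acyltransferase, rose from 6.72 ± 3.10 to 68.5 ± 9.66 CPM (adjusted p = 0.00268 and 0.00614). Both passed with every library left out in turn. Fkbp5 had 451 ± 36.9 CPM in controls and 619 ± 75.2 CPM in hormone libraries and did not pass (adjusted p = 0.132). Only DESeq2 called Fkbp5 (adjusted p = 0.0245). Of 24 estrogen receptor target genes tested, 4 rose and 1 fell (10 and 1 when adjusted over the list alone). Il1r1, the interleukin-1 receptor, the secreted glycoprotein Stc2 and the growth factor Tgfa rose by 1.79, 1.98 and 1.32 on the log2 scale, and the amino acid transporter Slc7a5 fell by 0.81. The lipid transporter Abca3, named after its values were seen, rose by 1.21. The first 4 calls were each lost without control 2 and without hormone 1, and those of Stc2, Tgfa and Slc7a5 also without hormone 2 or 3 (adjusted p up to 0.0908 for Tgfa, which was lost without control 1 too). Camera gave an adjusted p of 0.00254 for both lists, and both had adjusted p = 0.602 with an estimated correlation. Many lists share this 0.602 after the Benjamini-Hochberg adjustment, so equal values do not mean equal evidence. The unadjusted camera p with an estimated correlation was 0.0508 for the androgen-responsive list and 0.138 for the estrogen receptor target list.

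The gene with the largest share of counts differed by group, Tgm4 in each control and Fcgbpl1 in each hormone library. Tgm4, the prostate transglutaminase that forms the copulatory plug, took 10.2% ± 2.70 of control counts and 9.09% ± 1.25 of hormone counts (exact permutation p = 0.6). Fcgbpl1, an IgG Fc-binding protein-like gene chosen after its values were seen, took 4.24% ± 1.54 and 11.7% ± 0.75 (exact permutation p = 0.1, the smallest that 3 against 3 can give; edgeR log2 fold change 1.57, adjusted p = 0.0731). The list of androgen-dependent prostate secretory genes took 10.6% ± 2.68 of control counts and 9.47% ± 1.03 of hormone counts (exact permutation p = 0.6). Of its 7 members tested, Sbp, the spermine-binding protein, rose from 1.86 ± 0.95 to 49.4 ± 33.9 CPM (adjusted p = 0.0119), a call lost without control 2 (adjusted p = 0.0636). Msmb, beta-microseminoprotein, had 2713 ± 1148 and 891 ± 468 CPM (adjusted p = 0.128). Scgb2a1, a secretoglobin, ranged from 302 to 6232 counts in controls and from 1135 to 33734 in hormone libraries. Pbsn, probasin, was listed at 0 counts in all 6 libraries, as was the broadly expressed transcription factor gene Mtf1, so a 0 in this table need not mean an absent transcript. The seminal vesicle and coagulating gland list had 2 members tested, too few for camera. Semg1 took 0.112% to 2.39% of counts in controls and 0.324% to 0.866% in hormone libraries, and Pate4 had 3066, 763 and 1 counts in controls 1, 2 and 3 and 0 in each hormone library. The sample titles say prostate tissue and name no lobe. Whether all libraries hold the same part of the gland was not tested. The 10 most abundant genes held 20.6% ± 3.32 of control counts and 26.2% ± 1.30 of hormone counts.

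Lists of macrophages, T and NK cells, B cells, interferon response and antigen presentation had higher values in hormone libraries as groups, while few single members passed and the mast cell and eosinophil list went the other way. None of these lists passed camera with an estimated correlation (adjusted p = 0.602 for each), most of their members were highest in hormone 1, and the B cell list did not pass without that library (0.0683). In the macrophage and dendritic cell list all 28 members tested had a positive fold change, with a median of 1.05, and 0 passed over all genes (22 rose when adjusted over the list alone). Irf8 and Cd68 in that list had 19.9 ± 4.33 and 14.0 ± 6.71 CPM in controls and 52.2 ± 21.1 and 36.9 ± 12.3 CPM in hormone libraries. All 34 interferon response members had a positive fold change, with a median of 1.13, and 0 passed (17 when adjusted over the list alone). Irf7 had 32.8 ± 7.79 and 114 ± 83.0 CPM and Usp18 had 11.5 ± 3.76 and 48.9 ± 32.2 CPM. Usp18, Irf8 and Cd68 passed with DESeq2, and Irf8 also with the replicate block. DESeq2 also called other members of these lists that the rule names. In the MHC and antigen presentation list 1 of 23 rose (11 when adjusted over the list alone), namely B2m, the light chain of MHC class I, from 3800 ± 810 to 9678 ± 1104 CPM (adjusted p = 0.0316). Cd74, the invariant chain, had 253 ± 53.9 and 555 ± 195 CPM (adjusted p = 0.0696). The T and NK cell list had 0 of 23 past the test (4 when adjusted over the list alone) and a median of 0.96, and the B and plasma cell list had 0 of 8 (3 when adjusted over the list alone) and a median of 0.95.

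Among inflammatory mediators, 1 of 29 NF-kB list members rose (7 rose and 1 fell when adjusted over the list alone), namely Sele, the endothelial adhesion molecule E-selectin, from 0.364 ± 0.11 to 2.08 ± 0.60 CPM (adjusted p = 0.0238). In the complement list 1 of 22 rose (3 when adjusted over the list alone), the central component C3, from 6.67 ± 1.63 to 112 ± 114 CPM (adjusted p = 0.0333). The cytokine and chemokine list had 0 of 27 past the test (7 when adjusted over the list alone), with Cxcl9 at 9.86 ± 1.41 and 32.5 ± 19.6 CPM, and Il6, interleukin-6, had 1 count over the controls and 5 over the hormone libraries. Cxcl9 passed with DESeq2 and with the replicate block. Tgfb1 had 25.6 ± 5.60 and 42.2 ± 14.2 CPM (adjusted p = 0.166). Camera adjusted p values were 2.88e-10 for macrophages, 8.55e-09 for interferon response, 4.02e-06 for antigen presentation, 0.000104 for T and NK cells, 0.00243 for NF-kB, 0.00687 for complement, 0.0136 for B cells and 0.0154 for cytokines. With an estimated correlation the adjusted p was 0.602 for the first 7 of these and 0.67 for cytokines. Of the 194 members tested of these 8 lists, 90.2% had their highest hormone value in hormone 1, where an even spread gives 33.3%. Members of these lists moved together, with estimated correlations of 0.374 to 0.740, so 33.3% is not a chance level for them. The share over all genes tested was not computed. Without hormone 1 camera no longer passed for NF-kB (0.0735), complement (0.0579), B cells (0.0683) and cytokines (0.154). Without control 3 it no longer passed for complement (0.101), B cells (0.0609) and cytokines (0.154). The call of B2m was lost without control 2, control 3 or any hormone library (adjusted p up to 0.121), that of Sele without any 1 library (up to 0.095), and that of C3 without any control or hormone 3 (up to 0.113). B2m and C3 also lost their calls in the 3 limma settings on FPKM, and C3 with no filter and with the replicate block. The haemoglobin gene Hba-a1 had 157 ± 69.0 and 267 ± 41.7 CPM and did not pass (adjusted p = 0.206). The red blood cell list had 0 of 7 past the test and a camera adjusted p of 0.0411 (adjusted p = 0.615 with an estimated correlation). It was lost without control 3 (0.179), hormone 1 (0.0899) or hormone 2 (0.107).

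Lists of mast cells and eosinophils, which are immune cells, and of fibroblasts, smooth muscle and adipocytes had lower values in hormone libraries, while the matrix and endothelium lists did not pass camera. In the mast cell and eosinophil list 9 of 10 members had a negative fold change, with a median of -1.36, and 0 passed (9 fell when adjusted over the list alone). The mast cell carboxypeptidase Cpa3 had 20.9 ± 10.4 and 5.96 ± 1.79 CPM. Cpa3 passed with DESeq2 and without control 1. The fibroblast list had 0 of 21 past the test (4 fell when adjusted over the list alone) and a median of -0.45, with Lum, the proteoglycan lumican, at 203 ± 72.4 and 89.6 ± 9.76 CPM. Lum passed with DESeq2 and without control 3. The smooth muscle list had 0 of 22 past the test, also when adjusted over the list alone, and a median of -0.39, with Mylk, myosin light chain kinase, at 844 ± 374 and 507 ± 171 CPM. In the adipocyte list 0 of 14 passed (3 fell when adjusted over the list alone), and the median was -0.93. Camera adjusted p values were 0.000104, 0.0011, 0.00449 and 0.0347 for these 4 lists, and 0.602, 0.602, 0.717 and 0.602 with an estimated correlation. Control 1 had the highest share of counts from mitochondrially encoded genes, 7.80%, against 3.40% to 4.97% in the other libraries. Without it the smooth muscle list no longer passed camera (0.252), and the adipocyte list was lost without control 1 (0.0558), control 2 (0.270) or hormone 1 (0.0683). The adipocyte call was weaker under 13 of 19 alternatives, among them quantile normalisation (0.124), the 3 limma settings on FPKM (0.454 to 0.585), FPKM of at least 5 (0.988), the replicate block (0.0627) and removal of the length trend (0.180). The collagen and extracellular matrix list had a median of 0.14 (camera adjusted p = 0.343, and 0.0499 without control 2). The endothelium list had a median of 0.18 (0.343, and 0.005 without control 1). Kdr, the main VEGF receptor, was its 1 member of 22 that rose, from 13.5 ± 3.78 to 28.2 ± 2.89 CPM (adjusted p = 0.0444), a call lost without control 2, control 3 or any hormone library (up to 0.132).

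Epithelial lists gave mixed values. Krt8, a luminal keratin, rose from 264 ± 22.8 to 509 ± 49.7 CPM (adjusted p = 0.0164), the 1 member of 23 in the luminal list that passed (camera adjusted p = 0.906). It lost its call without control 2 or any hormone library, with an adjusted p of up to 0.0821. Krt5, a basal keratin whose listed span overlaps other keratin genes, had 187 ± 73.6 and 113 ± 28.3 CPM (adjusted p = 0.213). In the squamous keratinization list 2 of 12 rose (5 rose and 1 fell when adjusted over the list alone), the keratin Krt80 and the envelope protein envoplakin (Evpl), by 3.32 and 1.14 on the log2 scale (adjusted p = 0.0129 and 0.0175). Both were lost without control 2 (0.0636 and 0.0753), and Evpl also without hormone 2 or 3. The list passed camera at 0.0297 with a median of 0.17 (adjusted p = 0.602 with an estimated correlation) and did not without control 3 (0.0667), with quantile normalisation (0.124), with no filter (0.0648), on ranks (0.224), on log2 CPM (0.146) or with the length trend removed (0.148). Of 34 oxidative phosphorylation members, 30 had a negative fold change, with a median of -0.24. The ATP synthase subunit gene Atp5mc1 fell from 62.9 ± 4.11 to 41.9 ± 3.68 CPM (adjusted p = 0.0393), 1 of 34 over all genes and when adjusted over the list alone. It did not pass with any 1 library left out (up to 0.142). Camera gave 0.000323 for this list, and adjusted p = 0.602 with an estimated correlation.

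**Figure D2:**
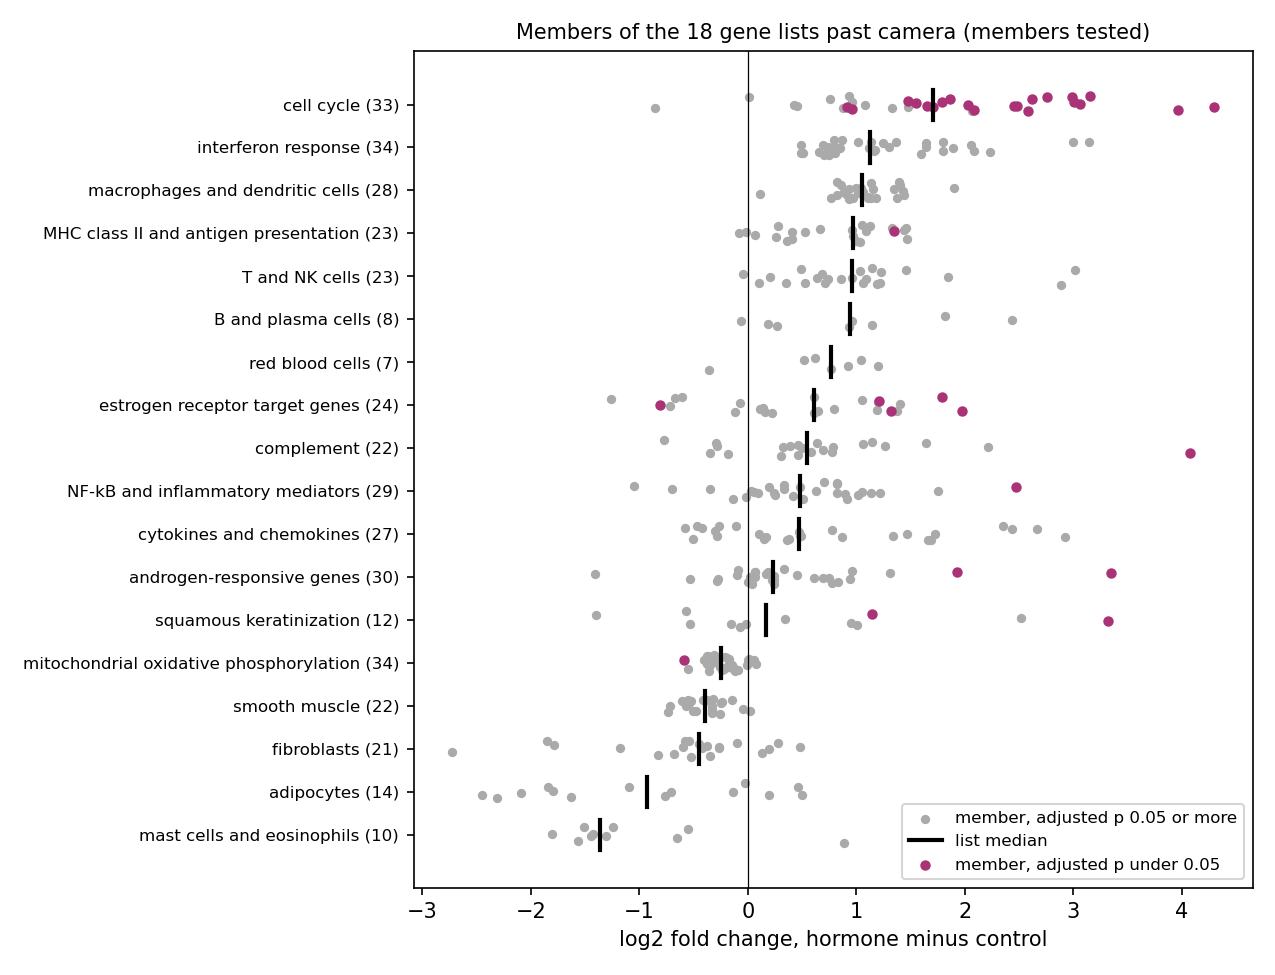
Log2 fold changes (hormone minus control) of the members tested of the 18 gene lists past camera, with 1 point per gene, members past the gene test in purple and a black bar at each list median. Most purple points belong to the cell cycle list (21 of 33 members, median 1.71). The macrophage, T and NK cell and B cell lists have medians near 1 and the mast cell and eosinophil list a median of -1.36, with all members of these 4 lists in grey.

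The other lists did not pass camera. The apoptosis list had a median of 0.16 and 0 of 23 members past the test, with Bax at 31.1 ± 11.1 and 23.5 ± 1.43 CPM (adjusted p = 0.351) and Bcl2 at 2.49 ± 0.93 and 2.61 ± 0.75 CPM (adjusted p = 0.935). Of 29 growth factors and receptors, Tgfbr1, a TGF-beta receptor, rose by 0.63 on the log2 scale and Vegfa, the vascular growth factor, fell by 0.76 (adjusted p = 0.0366 and 0.0497). Without control 1, control 2 or any hormone library neither passed, and Tgfbr1 also not without control 3 (adjusted p up to 0.143 and 0.155). Both were also lost with no filter and in the 3 limma settings on FPKM. Tgfbr1 was lost with the replicate block too, and Vegfa with FPKM of at least 5. In the antioxidant list the peroxiredoxin Prdx6 fell from 751 ± 89.6 to 313 ± 99.7 CPM (adjusted p = 0.0461; lost with any 1 library left out, up to 0.127), and in the list of ER chaperones the ubiquitin ligase Syvn1 fell from 1186 ± 177 to 594 ± 49.8 CPM (adjusted p = 0.0243; lost without control 2 or any hormone library, up to 0.12). Medians were -0.58 for nerve and Schwann cells, 1.02 for neutrophils, -0.67 for skeletal muscle, 0.22 for immediate early genes, 0.18 for cholesterol and fatty acid synthesis, 0.31 for basal epithelium and -0.16 for proximal luminal epithelium. The urothelium list (median 0.03, mean -0.01) and the polyamine list (median -0.20, mean 0.03) had a median and a mean of opposite sign. Some of these lists passed camera with 1 library left out, namely the nerve list in 4 of the 6 sets (lowest adjusted p = 0.0044), basal epithelium without control 1 (0.0116) and neutrophils without hormone 2 (0.0121). Others were ER chaperones without control 1 (0.00344) or hormone 2 (0.0408), the antioxidant list without control 2 (0.0305) or control 3 (0.0488), cholesterol synthesis without control 3 (0.0142), prostate secretory genes without hormone 2 (0.0408), and immediate early genes and skeletal muscle without hormone 3 (0.0239 and 0.0338). With all libraries, the nerve list passed with no filter (0.0317), a replicate block (0.0324) and ranks (0.0301), and the antioxidant list with no filter (0.0450) and ranks (0.0487). Skeletal muscle passed in the 3 limma settings on FPKM (0.0276 to 0.0376), and neutrophils with no filter (0.00573), on log2(FPKM + 0.1) (0.0489) and with the length trend removed (0.0409).

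The libraries grouped by treatment on the first principal component, but not in every correlation. The first principal component held 49.6% of the variance and separated the groups, and the second, with 20.3%, spread the controls and set hormone 1 (21.5) apart from hormone 2 and 3 (-6.65 and -4.18). Pearson correlations of log2 CPM were 0.954 to 0.979 within groups and 0.92 to 0.957 between groups. Control 3 correlated with hormone 2 and 3 at 0.957 and 0.955 and with control 1 at 0.954.

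**Figure D3:**
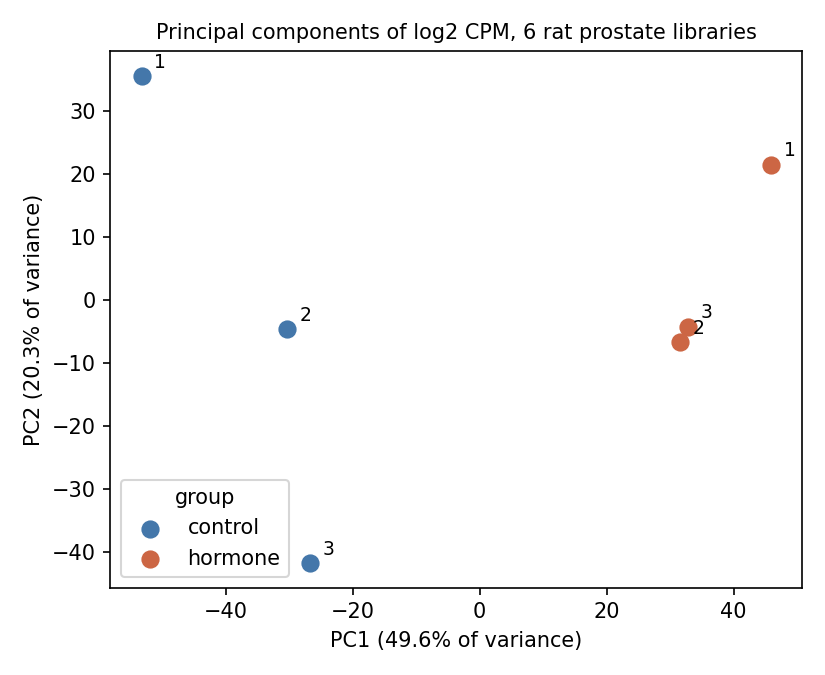
First and second principal components of log2 CPM over 14003 genes, 1 point per library, numbered by replicate and coloured by group. The first axis (49.6% of variance) places the 3 hormone libraries on one side and the 3 controls on the other, and the controls and hormone 1 spread along the second axis (20.3%).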

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

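Camera on log2 CPM and camera after removal of the gene length trend were chosen only after the results were seen. No named gene and no list turned its direction in a call made with the main settings or an alternative. DESeq2 size factors, quantile normalisation and no filter left the counts within 1.5 times of 334 higher and 124 lower genes. Requiring FPKM of at least 5 in at least 3 libraries gave 173 and 77 genes, with fewer genes tested (8822), and 7 higher and 3 lower lists. Limma on log2(FPKM + 1), log2(FPKM + 0.1) and log2(FPKM + 5) gave 174, 173 and 144 higher genes and 134, 136 and 114 lower ones, so that 56.5%, 56.0% and 55.8% of calls were higher against 72.9% with edgeR. With those values the median of all genes lay at -0.10, -0.12 and -0.07. FPKM values were not TMM-scaled, and the TMM factors were 1.006 to 1.086 in controls and 0.932 to 0.975 in hormone libraries. Leaving these factors out lowers hormone values against controls, which is the direction of the shift. Its part in the share of higher calls was not tested. DESeq2 gave 906 higher and 618 lower genes and called all 458. The cause was not tested. An adjusted p under 0.01 left 56 and 5 genes, and a 1.5-fold minimum 119 and 20. With 1 library left out, the count of higher genes ranged from 51 to 313 and that of lower genes from 12 to 156. Lists past camera ranged from 8 to 15 higher and from 4 to 7 lower. With an estimated correlation 0 higher and 0 lower lists passed, where the cell cycle list came closest, and fry called 2 higher and 0 lower lists (cell cycle and squamous keratinization).

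The replicate numbers are shared by both groups but the deviations from the group means did not go together, with correlations of 0.083, -0.057 and 0.07 for numbers 1, 2 and 3, and not every library correlated best with its own number. A fit with a replicate block gave 228 higher and 80 lower genes, with fewer residual degrees of freedom.

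Of 49 called genes that the rule names, 15 still passed without control 2, 37 without control 1, 38 without control 3 and 27, 24 and 27 without hormone 1, 2 and 3. With all libraries, 44 passed with no filter and 40 with the replicate block. Of the 48 with a value in limma, 40, 42 and 34 passed on log2(FPKM + 1), log2(FPKM + 0.1) and log2(FPKM + 5). With 1 library left out, the difference in counts taken by the prostate secretory list ranged from -2.66 to -0.179 percentage points, and that of the seminal vesicle list from -0.869 to 0.266, the sign changing without control 3. The mean correlation within groups exceeded that between groups by 0.027 (Pearson) and 0.0205 (Spearman).

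In simulated data 9.43% of genes changed 2-fold were called at or below the median level of 20.4 CPM and 61.7% above it, and of genes changed 4-fold 78% and 96%. Depth was not varied, so its part in this was not tested, and a gene that did not pass is not shown to be equal in both groups.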

Other observations

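The tests and genes of this part were chosen only after the results were seen. Of the genes in its first 2 paragraphs, only Csn2, Rbp7 and Aldh1a1 were run under the alternatives. The metallothioneins Mt2A and Mt1m, which bind zinc and copper, rose by 2.79 and 2.93 on the log2 scale (edgeR adjusted p = 0.00862 and 0.009). Hamp, the iron hormone hepcidin, rose 22.7-fold, from 3.19 ± 1.01 to 72.4 ± 27.7 CPM (adjusted p = 0.00396). The metal exporter Slc30a10 rose by 3.15 and the zinc importer Slc39a10 by 2.13 on the log2 scale (adjusted p = 0.00759 and 0.041), and Slc39a4 fell by 4.16 (adjusted p = 0.02). The zinc exporter Slc30a1 had a log2 fold change of 1.37 and did not pass (adjusted p = 0.07). Beside Csn2, Btn1a1 and Olah, known from milk secretion, rose by 3.60 and 2.90 (adjusted p = 0.0393 and 0.00991), while Csn1s1 had 3 counts over the controls and 0 over the hormone libraries, Csn1s2a had 2 and 9, and Csn3, Lalba and Wap were listed at 0 in all libraries. Plin2, also looked up, rose by 0.91 (adjusted p = 0.0266), and Cish had 0.75 and did not pass (0.0799). Of 4 retinoid genes looked up, Rbp7 rose, Rarb and Stra6 fell by 1.45 and 1.31 (adjusted p = 0.023 and 0.0293), and Aldh1a1 had -1.05 and did not pass (adjusted p = 0.056).

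Per2, Tef and Hlf, which belong to the circadian clock and its output, fell by 1.12, 0.75 and 1.39 on the log2 scale (adjusted p = 0.0126, 0.0225 and 0.0384). The 7 other clock genes looked up did not pass, with log2 fold changes of -0.74 for Per3, -1.05 for Dbp, 0.02 for Per1 and 0.22 for Arntl (adjusted p = 0.057, 0.126, 0.966 and 0.484) and of -0.15 for Nr1d1, -0.25 for Nr1d2 and 0.27 for Clock (0.877, 0.532 and 0.684). Klhl22 rose from 91.4 ± 4.57 to 405 ± 29.3 CPM (adjusted p = 0.00157). Drosha, the nuclear microRNA processing enzyme, and the neighbouring RGD1306502 rose by 1.49 and 1.44 (adjusted p = 0.00652 and 0.00442). Mt-atp6 had 83715 counts in hormone 3 and 13244 to 24467 in the other libraries.

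The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. As many genes were called by edgeR in 1 of the 10, the real one, with 458 genes and at most 0 in another split (3188 and at most 779 at an unadjusted p under 0.05). Each other split mixes hormone and control libraries on both sides, so a group difference widens the spread within its sides. Few calls there are expected whenever the groups differ. The contrast therefore does not measure how often 458 genes would be called without a difference. As many lists passed camera in 5 of the 10, with 18 in the real split and at most 19 in another. The other splits keep part of any group difference, so their lists need not have passed without one.

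The first pattern is the rise of the metallothionein genes. Mt1 (chromosome 17, 78793336 to 78793724, within the span of Dclre1c), Mt1m (chromosome 20, 3677474 to 3677847), Mt2A and AC128848.1 (chromosome 19, 11307967 to 11308740 and 11302125 to 11302938) belong to a family of similar sequences, so reads could be assigned to the wrong copy. The sum over the 4 ranged from 431 to 795 CPM in controls and from 3133 to 4314 CPM in hormone libraries, a log2 difference of 2.54, which an exchange of reads among these copies would leave near 0. A single library did not carry it, since the lowest log2 difference with 1 library left out was 2.32. Which copy was transcribed stays open, as does an effect of the hormone treatment, which was not tested further.

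The second pattern is the higher level of immune lists, whose members mostly had their highest hormone value in hormone 1. Without hormone 1, camera passed for 4 of the 4 lists of macrophages, T and NK cells, interferon and antigen presentation. It passed for 0 of the 4 lists of B cells, NF-kB, complement and cytokines (1 of these 4 without control 3). But no list passed with an estimated correlation (adjusted p = 0.602, and 0.67 for cytokines). Camera at the preset correlation passed 9 to 19 lists in the other splits, which keep part of any group difference. In mean log2 CPM of the members, the lower of hormone 2 and 3 was compared with the highest control. It lay above that control by at least 0.0434 in the first 4 lists and by -0.0785 or more in the other 4. SDs among controls were 0.181 to 0.483. The gap exceeded the list's own control SD for interferon response (0.245 against 0.228) and B cells (0.274 against 0.209), and for no other of these lists. The medians without hormone 1 were 0.44 to 0.75 and 0.20 to 0.70. Hormone 1 alone therefore stays open for each set as a whole, though the interferon and B cell lists went past the control SD without it. More blood in the hormone tissue would add haemoglobin above all, but the summed members of the first 4 lists, B2m left out, were higher by 2485 CPM and the haemoglobin genes by 184 CPM, and the lowest ratio with 1 library left out was 8.41. The haemoglobin genes are also a family of similar genes, and how reads shared among them were counted is not given. If such reads were dropped, the rise of haemoglobin is understated, so the ratio does not settle the part of blood. More immune cells under the pellets and a stronger response per cell stay open and were not tested.

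The third pattern is the lower oxidative phosphorylation list, which did not pass with an estimated correlation (adjusted p = 0.602) or with fry (0.199). Across genes, which are not independent replicates, log2 fold change and gene length had a Spearman correlation of 0.167, so a length trend could lower a list of short genes. After that trend was removed, the median went from -0.24 to -0.21 (quartiles -0.26 and -0.14), so the trend is not the whole of the difference (camera on log2 CPM 0.00357, against 7.3e-05 before). Without control 1 the median was -0.19 (camera 0.00136), but the lower of controls 2 and 3 lay above the highest hormone library by 0.0493 in mean log2 CPM, less than the SD of 0.0668 among hormone libraries, so control 1 alone stays open. An effect of the hormone treatment and a change in cell composition also stay open and were not tested.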
